A study of Halobacterium salinarum NRC-1 with 8 samples.

How the data were processed

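The files used were 8 scanner tables, one per array, and the value table of the series. Per the labels, each array carried the RNA of 1 culture in Alexa 532 or Alexa 647 and the standard NRC-1 reference RNA in the other dye, and the 2 arrays of a culture are a dye swap of the same RNA. Per the file headers, each scanner table gives for each spot the mean and median intensity, the median background intensity and its standard deviation at a high and a low scan of each dye, on a scale that ends at 65535, and a spot confidence in percent. Intensity per the file headers is the deposited, uncorrected value. The authors' deposited value table holds log10 values, whose making is not given in the sources used here. Set against the scanner values, its columns correlated at r 0.71 to 0.96 with the log10 of Alexa 532 over Alexa 647, so they are log10 ratios in that direction. Their medians were 0.07, 0.06, 0.08, 0.05, 0.06, 0.08, 0.10 and -0.07 for the high-oxygen light, high-oxygen dark, low-oxygen light and low-oxygen dark cultures, Alexa 532 array first. How they were centred or scaled stays unknown. At 469 spots 7 of the 8 columns were empty.

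Spots were placed by the block, row and column that the scanner tables give, in the order of the value table's probe numbers. In this order the 4 spots of a probe set are an adjacent pair in each part of the slide. Gene names came from the platform table given for this series: 532 probes have 1 symbol, 0 have several and 10220 have none, which makes 133 named genes and 2555 probe sets that are unnamed here. As a check of the placing, the csg probe set was the brightest of all probe sets (percentile 100), and the named genes had a median brightness percentile of 74.3. No 2 arrays held identical intensities.

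Between 102 and 749 spots per channel were saturated in the high scan. Spots over 40000 in the high scan were therefore replaced by their low-scan value, put on the high scan's scale by a linear fit over spots between 10000 and 40000. This choice was made after the files were seen, and the high scan alone and the low scan alone are alternatives. Background was corrected with normexp (offset 50), and log2 ratios were normalised within each array by loess (span 0.3, 4 iterations). Control spots could not be told from gene spots in the tables used, so loess ran over all spots, which departs from the plan to give control spots no weight. The tables hold no spot flags, so none were left out. The 4 spots of a probe set were averaged on the log2 scale, ratios were turned to culture over reference by the dyes in the labels, and the 2 arrays of a culture were averaged. A probe set counted as well above background on an array if at least 2 of its 4 spots had a median over the background median plus 2 background standard deviations in the high scan, a rule set after the files were seen. By it the culture channel had 20.1% to 81.3% of probe sets above background per array. The highest share is that of the low-oxygen dark array in Alexa 647, and the median intensity there was 15660, against 2597 to 5151 in that dye on the other arrays. Median intensity over median background was 1.71 to 3.06 over the arrays and dyes.

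Tests were run on 4 values per probe set, 1 per culture, with limma 3.58.1 in R 4.3.3 (files were read with the package data.table, version 1.17.8). An additive model with oxygen and light was fitted to all 4 cultures, which leaves 1 residual degree of freedom, and eBayes added 1.40 prior degrees of freedom. The tests were two-sided, with Benjamini-Hochberg adjustment over 2688 probe sets and a threshold of 0.05. The comparison with the reference tested the mean of the 4 cultures against 0. The labels do not say more of the cultures than their condition. The 1 residual degree of freedom is the oxygen by light difference of the 4 single cultures. Standard errors, intervals and p-values rest on it and on the prior, and do not measure a spread between replicate cultures. With 1 culture per condition the oxygen by light difference and the correlations between effects were given without a test. Replicate numbers pair no samples here, since each condition has 1 culture. Gene lists were fixed in advance. Of 27 lists, 10 had no measured gene, 8 had fewer than 4 and are described by genes only, and 9 were tested with camera (preset correlation 0.01, the 133 named genes as background), beside an estimated correlation and fry. The lists without a measured gene were gas vesicles, DMSO and TMAO respiration, terminal oxidases, ATP synthase, RNA polymerase, general transcription factors, potassium transport, iron uptake, peptide and amino acid transport, and transposases. The planned list of plasmid genes was not used here.

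Named genes followed a rule fixed in advance: sop2 and ura3 always, then, for each comparison, up to 10 genes per direction among those past the threshold with 1 sign in all single values (8 arrays, or 4 differences between cultures within a dye orientation), filled from genes not passing, then up to 4 members of each list with a value, and the largest oxygen by light differences. The rule was applied to the 133 named genes alone. The largest oxygen by light differences all belonged to unnamed probe sets, so the rule names no gene for them.

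The scripts were tested on simulated data with known changes in 100 probe sets per size. For the reference comparison 68% of log2 changes of 1 and 95% of changes of 2 were recovered with 9 false calls among 2688 probe sets. For oxygen it was 2% and 80% with 4 false calls, and for light 1% and 76% with 2 false calls. The simulated dye effect was the same in every culture and cancelled within each, which it did not in the real low-oxygen dark culture. These shares may therefore be too high for the real arrays. All 9 lists passed camera when moved by 1, and 0 others did. Of 200 simulated oxygen by light differences of 2, 89.5% were counted at a size of 1, with 47 counted among unchanged probe sets.

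Alternatives set before the data were examined were no background correction, plain subtraction, median centring, scaled arrays, the deposited value table, dim probe sets left out (lowest 25 percent by intensity), the median of spots, each array or culture left out, the 8 arrays with a dye term and a culture block, the tested factor alone, eBayes with a trend or robust, other list tests, and a size of 0.58. Added after seeing the data were each scan alone, loess within print blocks (span 0.4), spots with a confidence under 50 left out (5.61% of spots, of which 83.1% were at the top of the scale), only probe sets above background on all 8 arrays, each dye orientation alone for the large oxygen by light differences, and all probe sets as the background of the lists. The dye part of a culture is the difference between its Alexa 647 and Alexa 532 arrays divided by 2. The dye part and culture part of a single array are its coefficients on the mean dye part and mean ratio of the other 3 cultures.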

Results

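Transcript abundance was measured in Halobacterium salinarum NRC-1, a salt-loving archaeon, with 8 spotted microarrays that each carried 10752 spots. The labels describe 4 cultures of a strain without ura3 and without sop2, the gene of sensory rhodopsin II, a photoreceptor of the repellent response to blue light. The strain was grown in rich medium to mid-log phase with much oxygen (shaking at 210 rpm) or little oxygen (100 rpm), each in light and in dark. There was 1 culture per condition. Each culture was hybridised to 2 arrays against RNA of a standard mid-log NRC-1 reference, once in each dye orientation. The 2 arrays of a culture are technical, so n is 4 cultures throughout, and the number of cultures limits the precision. The spots form 2688 probe sets of 4 spots each, and 133 of them carry a gene name here. The culture's RNA was well above background for 519 probe sets on all 8 arrays, 47 of them named.

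Across genes the dye left a strong mark on the ratios. The log2 ratio of culture over reference correlated across probe sets at a mean r of 0.70 between arrays of the same dye orientation (9 pairs) and at -0.05 between opposite orientations (12 pairs). Over the brightest 25% of probe sets the means were 0.79 and 0.40. The Alexa 647 array of the low-oxygen dark culture stood apart and is not in those pairs. Its Alexa 647 background had a median of 6960.75, against 1066 to 2356 on the other arrays. On it 126 of the 133 named genes were well above background in the culture, and the remaining 7 were so on no array. A named gene given as well above background in the culture on 1 array was therefore so on this array alone. The array correlated at 0.08 with its own orientation and at 0.55 with the opposite one. In the authors' deposited value table its correlation with its own orientation was -0.57, and with the opposite one 0.81. The labels state the dyes of each array, so the direction of its ratios was kept.

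**Figure D1:**
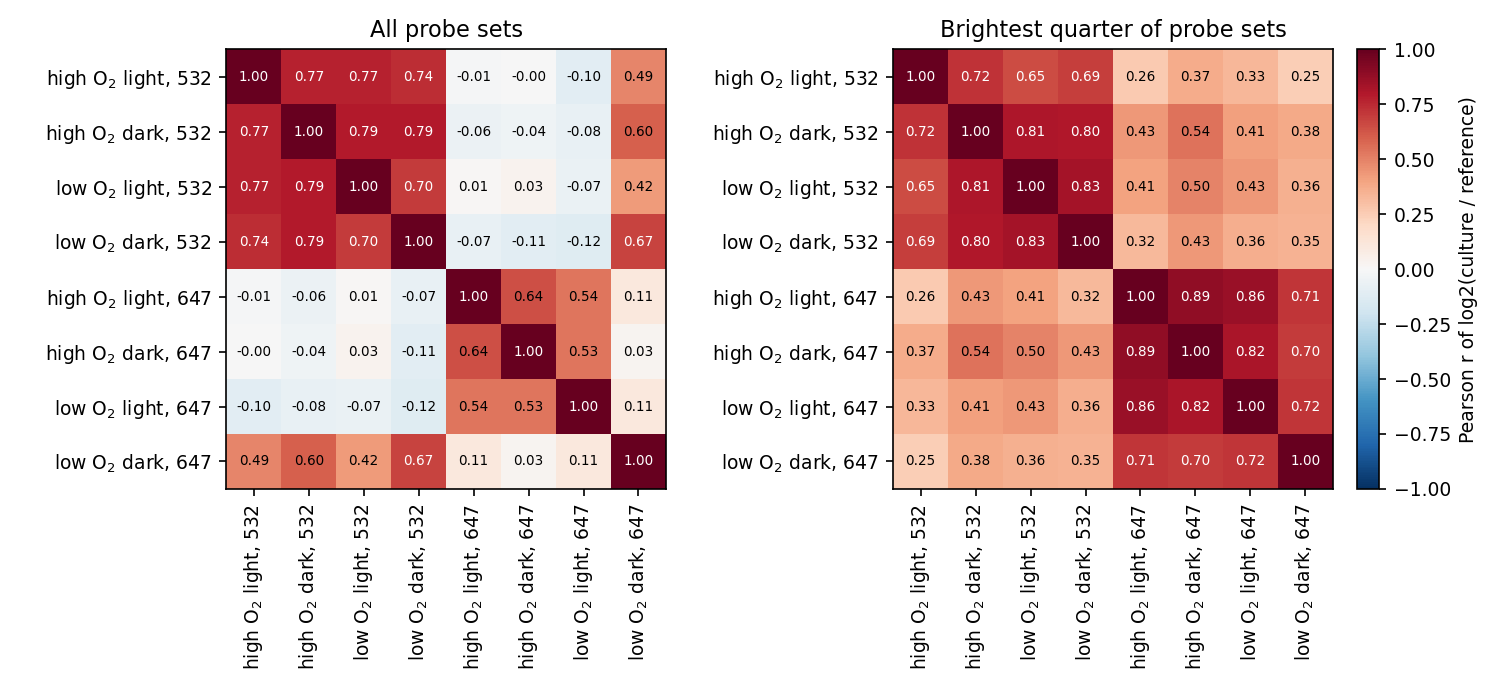
Pearson r of log2(culture / reference) across probe sets for every pair of the 8 arrays, named by culture condition and by the dye of the culture's RNA in nm, over all probe sets (left) and over the brightest 25% (right). Arrays of the same dye form blocks, and the low-oxygen dark array in Alexa 647 joins its own block over the brightest 25%, at a mean r of 0.71, but not over all probe sets, at 0.08.

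The genes that the labels give as deleted were looked at first. The sop2 probe set gave a log2 ratio of culture over reference of -0.06 ± 0.03 (SD, n = 4 cultures), with a 95% interval from limma of -0.23 to 0.12. It was lower than the reference on 4 of 8 arrays, with single arrays between -0.25 and 0.08. Its spots were well above background in the culture on 6 arrays and in the reference on 4. At the sop2 spots the culture channel stood on average at 4.57 times its background, and the reference channel at 4.08 times. This goes against the label of a sop2 knockout, so the cultures are named below as labelled sop2 and ura3 knockouts. Where the probe lies within the gene is not given in the sources used here, and a probe outside the deleted part would check nothing. For ura3, the labels' name for the gene of orotidine phosphate decarboxylase in uracil synthesis, the probe set named pyrF was taken. The pyrF ratio was -0.45 ± 0.12 (SD, n = 4 cultures) and lower than the reference on 7 of 8 arrays. It was well above background in the culture on 1 array, the one that stood apart, and in the reference on 0. Its mean was -0.11 with the culture in Alexa 532 and -0.80 with the culture in Alexa 647. Its direction therefore rests on dim spots. Of the related receptor genes, htr2, the transducer of sensory rhodopsin II, stood at 0.00 and sop1, sensory rhodopsin I, at 0.08.

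**Figure D2:**
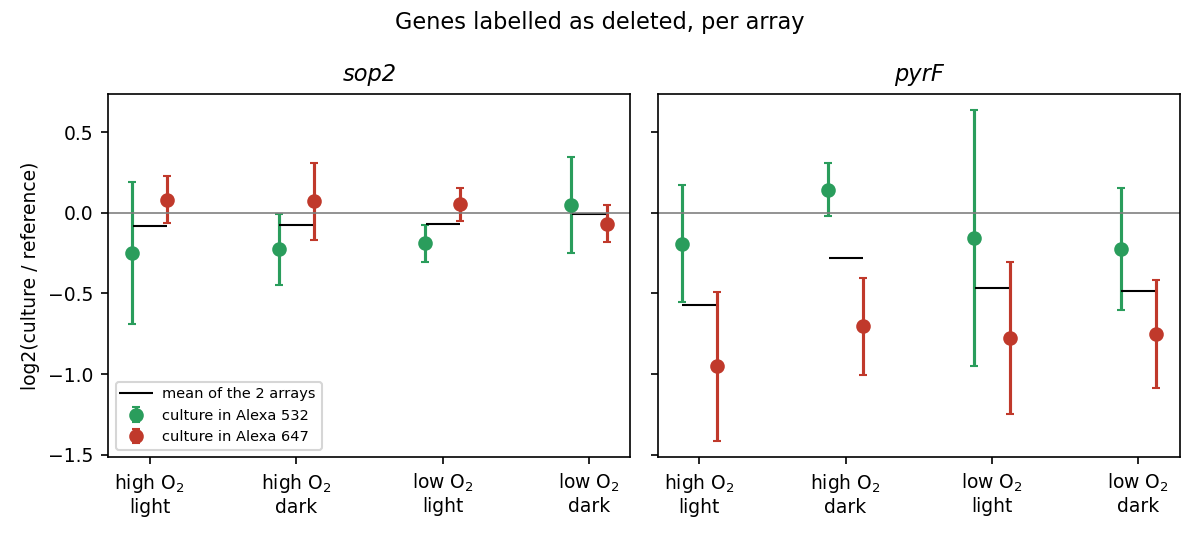
Log2 ratio of culture over reference for sop2 (left) and pyrF (right) on each of the 8 arrays, by culture condition. Points are means of 4 spots, error bars are the SD between these spots, colours give the dye of the culture's RNA, and black marks are the mean of the 2 arrays. The sop2 points lie between -0.25 and 0.08, and the pyrF points lie lower with the culture in Alexa 647 than in Alexa 532.

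All 4 cultures were set against the reference RNA to see what strain and growth had in common. The gene of the ribosomal stalk protein, rpl12p, stood at -0.89 ± 0.05 (limma SE, n = 4 cultures) and below the reference on all 8 arrays, from -1.40 to -0.49. Another ribosomal protein gene, rpmC, stood at -0.58 ± 0.07, and infB, a translation initiation factor, at -0.39 ± 0.08, both below the reference on all 8 arrays. Of these, infB was well above background on 5 arrays in the culture and on 4 in the reference. On the higher side, argH, argininosuccinate lyase of arginine synthesis, stood at 0.33 ± 0.05, and arcC, carbamate kinase of arginine fermentation, at 0.27 ± 0.05, both above the reference on all 8 arrays.

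All 6 measured genes of the citric acid cycle had negative means, with a list mean of -0.19 and the lowest values at sucC, succinyl-CoA ligase (-0.35 ± 0.05), citZ, citrate synthase (-0.31 ± 0.05), and mdh, malate dehydrogenase (-0.30 ± 0.05). In the fit, 0 of the 6 passed over all probe sets, and 3 passed when adjusted over the list alone. All 4 genes of cobalamin synthesis had negative means (list mean -0.18), led by cbiT (-0.41 ± 0.05) and cbiG (-0.28 ± 0.05), and 2 of these passed when adjusted over the list alone. In total, 13 named genes lay below the reference on all 8 arrays. Among those not yet given were hemA of heme synthesis (-0.34), and gdhA1 and gdhA2, glutamate dehydrogenases (-0.31 and -0.26). Of these, gdhA2 was well above background in the culture on 2 arrays. Others were speB, an agmatinase (-0.29), carB of carbamoyl phosphate synthesis (-0.30), and gyrB, a DNA gyrase subunit well above background on 1 array (-0.37). The 4 chemotaxis genes had positive means, with cheA, the signalling kinase, at 0.11 ± 0.06 and above the reference on all 8 arrays, but this list's mean turned negative with median centring, with the low scan and in the deposited table. Higher on all 8 arrays was also hutI of histidine use (0.41), but it was well above background in the culture on 1 array and in the reference on 0, and alternatives gave 0.16 to 1.46, so its size is not settled. Of the 12 tRNA ligase genes, 7 were lower and 5 higher, and of 9 receptor and transducer genes 7 were higher.

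**Figure D3:**
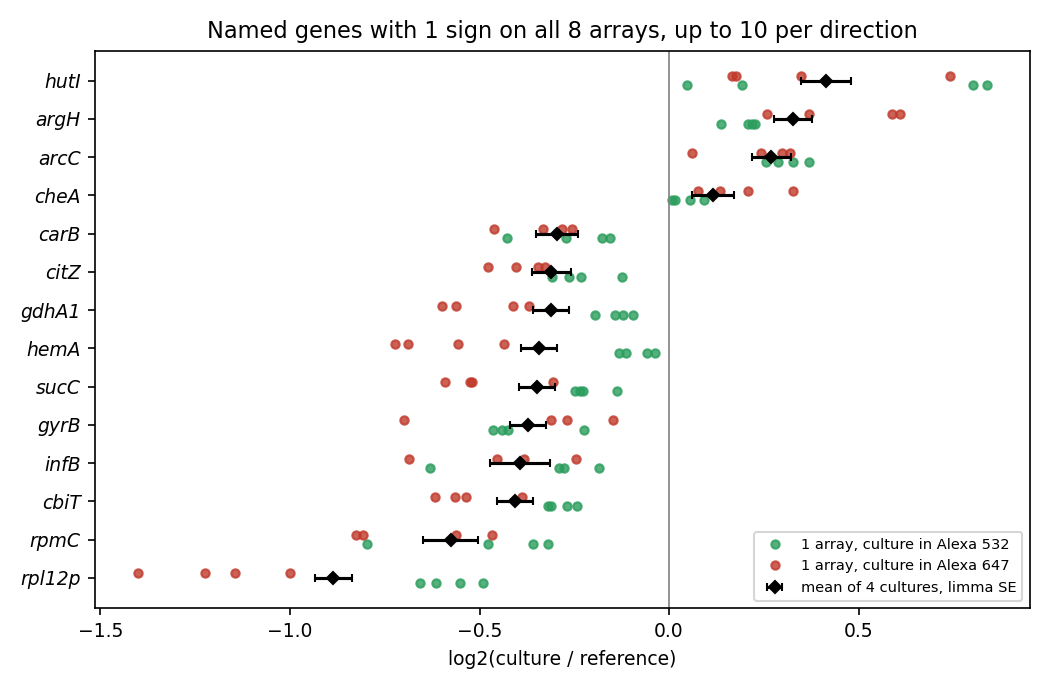
Log2 ratio of culture over reference for 14 of the 17 named genes with the same sign on all 8 arrays, up to 10 per direction. Each point is 1 array, coloured by the dye of the culture's RNA, and diamonds are the mean of 4 cultures with its limma SE. The gene rpl12p lies lowest, at -0.89. The highest, hutI at 0.41, was above background in the reference on 0 arrays.

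In limma, 0 of 2688 probe sets passed an adjusted p of 0.05 against the reference, with a smallest adjusted p of 0.143. At an unadjusted p under 0.05 there were 762 probe sets (369 higher, 393 lower), where chance gives 134.4. With 1 residual degree of freedom the fit recovered 68% of simulated log2 changes of 1, in data where the dye cancelled within each culture. An alternative fit with all 8 arrays, a dye term and the culture as a block called 1054 probe sets (487 higher, 567 lower), 41 of them named. In it rpl12p had an adjusted p of 0.00153, rpmC 0.00476, cbiT 0.00265, citZ 0.00462, argH 0.00476 and arcC 0.0072 in limma. That fit counts the arrays of a culture almost as separate samples, at an estimated correlation within cultures of -0.11. Without the Alexa 647 array of the high-oxygen dark culture, which leaves the dye uncancelled there, 232 probe sets passed, and with median centring in place of loess 444 did (162 higher, 282 lower). A sign shared by all 8 arrays was seen in 398 probe sets (172 higher, 226 lower). Among the 519 probe sets well above background on all arrays it was seen in 155. Among the 133 named genes taken alone, 0 passed in limma (29 at an unadjusted p under 0.05), and of the 67 genes of the fixed lists 9 passed when adjusted over the list alone, list by list, and 2 (rpl12p, purB) when adjusted over all 67 at once. Strain, growth and the making of the reference cannot be told apart, since each culture differs from the reference in all of them, and the reference's own spread is not in the test.

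Of 27 fixed gene lists, 9 held at least 4 measured genes and were tested with camera. Against the reference 0 of the 9 passed, with the citric acid cycle at an adjusted p of 0.218 and cobalamin synthesis at 0.265. With an estimated correlation also 0 passed in each of the 3 comparisons, so camera made no call that could be lost. The citric acid cycle list passed in the deposited table and with the low scan alone, and cobalamin synthesis in the deposited table. These calls did not hold with an estimated correlation (adjusted p = 0.757, 0.784 and 0.757 with an estimated correlation, in that order). With 1 residual degree of freedom that test could pass hardly any list, so it cannot decide on these calls. By fry, which tests whether a list's own genes move on balance in 1 direction, purine synthesis alone passed (adjusted p = 0.0329 in limma). Its mean was 0.04 and its median -0.12, since purB at 0.80 ± 0.05, well above background on 1 array, stood against lower values at purF (-0.23 ± 0.13), purL (-0.17 ± 0.05) and purD (-0.15 ± 0.05). By fry's mixed test, for change in either direction, 3 lists passed, namely tRNA ligases, cobalamin synthesis and purine synthesis.

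Low oxygen was compared with high oxygen over light and dark. In the main fit no named gene well above background on all 8 arrays differed by more than 0.22, the size reached by icd, isocitrate dehydrogenase of the citric acid cycle (-0.22 ± 0.09, limma SE, n = 4 cultures). Alternatives gave -0.51 to 0.01 for icd and -0.40 to 0.40 for cheB, a chemotaxis gene as bright. In the main fit mdh, malate dehydrogenase (-0.17 ± 0.11), and csg, the gene of the surface glycoprotein that forms the cell's outer layer (-0.12 ± 0.09), were also lower. On the higher side at low oxygen, purL of purine synthesis stood at 0.37 ± 0.10, with all 4 single differences between 0.27 and 0.51, and it was well above background on 7 arrays. Likewise phoU, a regulator of phosphate uptake, stood at 0.14 ± 0.09. Dimmer genes with the same sign in all 4 single differences were hisF of histidine synthesis (0.37 ± 0.15, above background on 5 arrays), serS, a tRNA ligase (0.23 ± 0.10, 3 arrays), and truA, which modifies tRNA (-0.38 ± 0.10, 1 array). The others by the rule were nadA (0.16), ileS (0.10), gyrB (-0.19), hisG (-0.17), cca (-0.16) and cheB (-0.09). Of these 14 genes, hisF, purL and hisG kept their sign under every alternative that gave them a value, but not their size, with 0.045 to 0.56 for hisF, 0.15 to 0.49 for purL and -0.28 to -0.06 for hisG. Since the 14 were chosen for 1 sign in all single differences, leaving out a culture could not turn it.

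The 9 receptor and transducer genes had a mean of -0.01 (4 higher, 5 lower), the 4 cobalamin genes -0.01, and the 12 tRNA ligase genes 0.00. The 6 citric acid cycle genes had a mean of -0.05, with 3 higher and 3 lower. The 4 chemotaxis genes all had negative means (list mean -0.06), led by cheB, a methylesterase of adaptation (-0.09 ± 0.09), but their list mean turned positive with the low scan. The 2 DNA replication genes, too few to test as a list, had a mean of -0.24, with orc7 at -0.33 ± 0.10 (above background on 3 arrays) and orc8 at -0.16 ± 0.10 (1 array). The 6 purine synthesis genes had the largest list mean, 0.26, and a median of 0.05. The mean rests on purB, at 1.26 ± 0.09, which was well above background on 1 array and whose single differences did not share a sign. In camera 0 of 9 lists passed, with purine synthesis at an adjusted p of 0.254, and fry called 0. Purine synthesis passed in camera without the Alexa 532 array of the high-oxygen light culture (adjusted p = 0.00953), without the Alexa 647 array of the low-oxygen light culture (0.0273) and without that of the low-oxygen dark culture (0.0025). These calls, each with the dye uncancelled in 1 culture, did not hold with an estimated correlation (adjusted p = 0.939, 0.96 and 0.994 with an estimated correlation, in that order). That test, with 1 residual degree of freedom, could pass hardly any list and cannot decide here either.

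In limma 0 of 2688 probe sets passed for oxygen (smallest adjusted p 0.984), and 58 had an unadjusted p under 0.05 (39 higher, 19 lower), where chance gives 134.4. The alternative with 8 arrays and a culture block also called 0, with 176 at an unadjusted p under 0.05. With median centring 1 passed. Adjusted over the list alone, list by list, 1 of the 67 list genes passed (purB, well above background in the culture on 1 array and in the reference on 0), and adjusted over all 67 at once 0 did. In 341 probe sets all 4 single differences shared a sign, where independent values would give 336. Among the 519 bright probe sets the largest absolute log2 difference was 0.52, and their median 95% interval reached 0.36 to either side of the estimate. In simulated data the fit recovered 2% of log2 changes of 1 and 80% of changes of 2, so a log2 change of 1 in a single gene was mostly not detectable. There the dye cancelled within each culture, so these shares may be too high for the real arrays.

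Light was compared with dark over both oxygen levels. Among named genes well above background on all 8 arrays the largest difference in the main fit was at phoU, the regulator of phosphate uptake, at 0.23 ± 0.09 (limma SE, n = 4 cultures), with single differences from 0.09 to 0.32. In purine synthesis, purF, its first committed enzyme, stood at 0.46 ± 0.25 in light and was well above background on 7 arrays, with single differences from 0.04 to 1.31. The gene panB of pantothenate synthesis stood at 0.19 ± 0.13. Lower in light were uvrB, of nucleotide excision repair (-0.22 ± 0.10), serB of serine synthesis (-0.13 ± 0.09), and mamA, a subunit of methylaspartate mutase (-0.57 ± 0.12), which was well above background on 1 array. Dim genes by the rule were dcd (0.28), gyrB (0.20), menD (0.18), hisF (-0.29) and nadA (-0.24), and small differences were seen at nuoL (0.05), cbiT (-0.10), pyrB (-0.09) and cheB (-0.04). For these last genes alternatives gave -0.10 to 0.47 (nuoL), -0.45 to 0.23 (cbiT), -0.17 to 0.40 (pyrB) and -0.14 to 0.41 (cheB). Of these 15 genes, purF, phoU, panB, mamA, hisF and uvrB kept their sign under every alternative that gave them a value, but not their size. As with oxygen, leaving out a culture could not turn the sign of genes chosen in this way. The alternatives gave 0.08 to 0.85 for purF, 0.10 to 0.43 for phoU, 0.06 to 0.33 for panB, -0.94 to -0.19 for mamA, -0.48 to -0.10 for hisF and -0.29 to -0.09 for uvrB.

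The sensory rhodopsin genes sop1 and sop2 stood at 0.03 ± 0.16 and -0.03 ± 0.10, and the transducer genes htr1 and htr2 at 0.06 ± 0.10 and 0.05 ± 0.10. The 9 genes of that list had a mean of -0.03 and a median of 0.03, with htr18 lowest (-0.45 ± 0.21, well above background on 1 array). The 6 citric acid cycle genes had a mean of -0.01 and the 4 chemotaxis genes one of 0.02. The 4 DNA repair genes had a mean of -0.08, with 3 lower, and the 4 chaperone and proteasome genes one of 0.05, with 4 higher. In the list of purple membrane genes, bat, the activator of bacterio-opsin transcription, stood at -0.44 ± 0.18 and hop, halorhodopsin, at 0.21 ± 0.09, each well above background on 1 array. In camera 0 of the 9 lists passed, with every adjusted p at 0.846, and fry called 0 and its mixed test 1, purine synthesis. With the low scan alone chemotaxis passed in camera (adjusted p = 0.0313), but not with an estimated correlation, at which hardly any list could pass. Alternatives gave this list means from -0.03 to 0.37.

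In limma 0 of 2688 probe sets passed for light (smallest adjusted p 0.976), and 75 had an unadjusted p under 0.05 (18 higher, 57 lower), where chance gives 134.4. The alternative with 8 arrays and a culture block called 0, with 192 at an unadjusted p under 0.05, and median centring called 2. Adjusted over the list alone, list by list, 0 of the 67 list genes passed, and adjusted over all 67 at once also 0. All 4 single differences shared a sign in 372 probe sets, where independent values would give 336. Among the 519 bright probe sets the largest absolute log2 difference was 0.38, and their median 95% interval again reached 0.36 to either side. In simulated data, where the dye cancelled within each culture, the fit recovered 1% of log2 changes of 1 and 76% of changes of 2. These shares too may be too high for the real arrays.

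**Figure D4:**
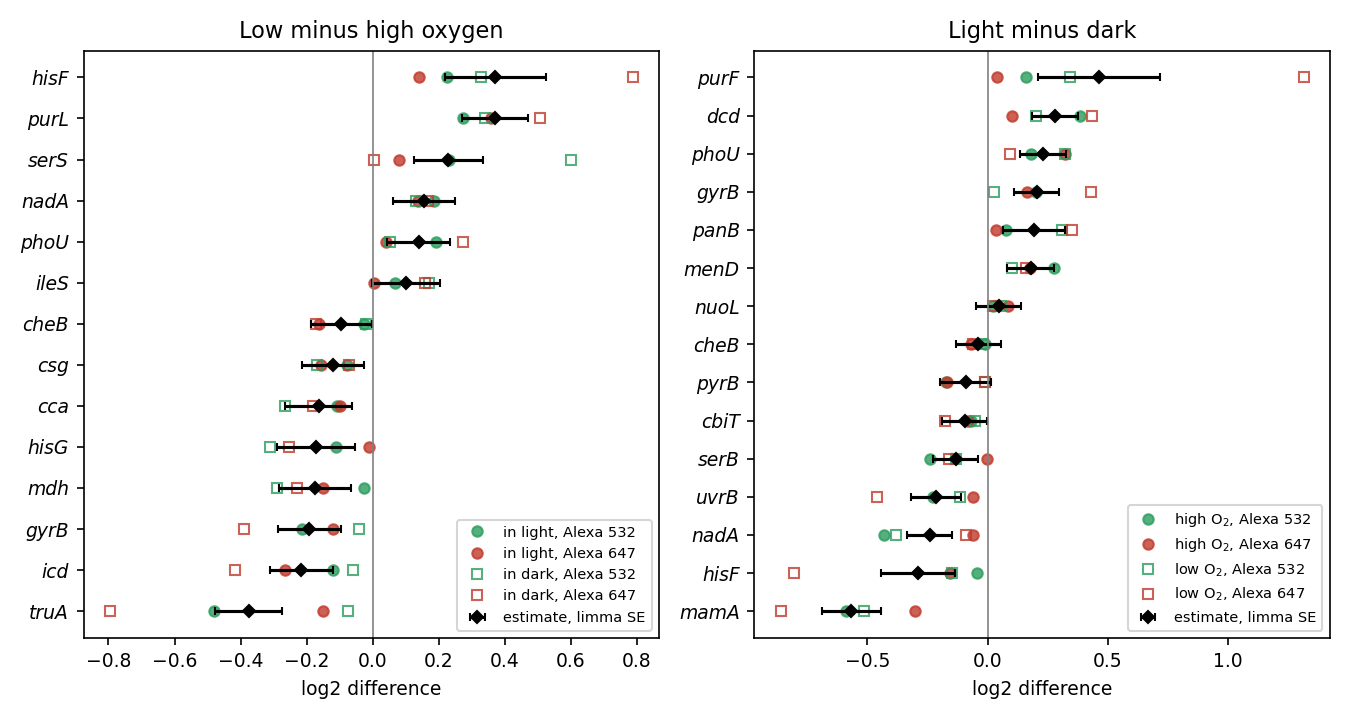
Log2 difference of low minus high oxygen (left, 14 genes) and of light minus dark (right, 15 genes) for the named genes whose 4 single differences share a sign. Circles and squares are single differences between 2 cultures within 1 dye orientation, coloured by the dye of the culture's RNA, and diamonds are the limma estimates with their SE. The estimates run from -0.38 for truA to 0.37 for hisF with oxygen, and from -0.57 for mamA to 0.46 for purF with light.

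Whether oxygen acted alike in light and in dark was looked at in named genes and across all probe sets. Of the 47 named genes above background on all 8 arrays, 25 differed with oxygen in the same direction in light and in dark and 22 in opposite directions, where independent signs would give 23.5. Among these were icd, at -0.19 in light and -0.24 in dark, and on the opposite side cheA (0.05 and -0.13), cheR (0.02 and -0.13) and sucD (-0.02 and 0.18). For light, 23 of the 47 differed in the same direction at high and at low oxygen and 24 in opposite directions. Across 2688 probe sets, which are not independent replicates, the oxygen difference in light and that in dark correlated at r = -0.22 (Spearman -0.15). Over the 133 named genes r was 0.22 (Spearman 0.03), and over the 519 bright probe sets it was 0.21. The r was 0.32 without the Alexa 532 array of the high-oxygen light culture and -0.43 without its Alexa 647 array, and for the low-oxygen light culture it was -0.38 and 0.14. Leaving out 1 array leaves the dye uncancelled in that culture, so dye may enter these values, which was not tested. Without the Alexa 532 array of the high-oxygen dark culture r was -0.22, and without its Alexa 647 array -0.14. Leaving out either array of the low-oxygen dark culture kept r within the range from -0.43 to 0.32. The light difference at high and at low oxygen correlated at 0.01 (Spearman -0.03), over named genes at 0.07 and over bright probe sets at 0.08. That value was -0.50 without the Alexa 532 array of the high-oxygen dark culture and 0.47 without its Alexa 647 array, where the dye is again uncancelled. Each effect was also compared between the dye orientations of the same cultures, over all probe sets. The oxygen difference correlated there at 0.04 in light and 0.37 in dark, and the light difference at 0.005 at high and 0.59 at low oxygen. The oxygen difference in light and the light difference at high oxygen thus hardly repeated on arrays of the same RNA. The r values between effects over all probe sets therefore say little about a response of the cells.

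A difference of at least 1 between the oxygen effect in light and that in dark, in each dye orientation alone, was counted in 160 probe sets (85 higher, 75 lower in light). None of the 133 named genes was among them, and 0 of the 160 were well above background on all 8 arrays. Almost all of the 160 were so in the culture on at most 1 array, and none on more than 3. Nearly all of the 85 higher ones lay in the last rows of the print blocks, so slide position cannot be told apart from a response there. In simulated data the dye effect cancelled within every culture, which it did not in the real low-oxygen dark culture. There 47 unchanged probe sets were counted at this size, which may be too low for the real arrays. At a size of 0.58 there were 289, with the named genes trpB of tryptophan synthesis (-0.85), nadC of pyridine nucleotide synthesis (-0.82) and hutG of histidine use (-0.62). These were named because they are few, after their values were seen, and each was well above background on at most 1 array. The count at a size of 1 was 5 without background correction and 10 with the low scan alone. When a single orientation had to reach that size, a laxer rule, it was 300 in Alexa 532 and 457 in Alexa 647, which holds the array that stands apart. With 1 culture per condition this difference has no test. Dye bias may enter it, which was not tested. The dye part of the array that stands apart was -0.51 where the other Alexa 647 arrays had 0.58 to 0.73.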

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

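The tests of the sop2 ratio, of the array that stood apart and of the correlation of oxygen effects were chosen after these results were seen. The oxygen effect in light and in dark, and the light effect at high and at low oxygen, were searched for genes whose differences in both dye orientations all lay on one side in the first condition and on the opposite side in the second. Among 77 genes this held for 10 oxygen effects and 9 light effects. Independent values in all 77 would give 9.625 for each. That figure is too high, since the 77 include 14 oxygen and 15 light genes chosen for sharing a sign in all single differences. None of these differences was tested, since there is 1 culture per condition.

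For oxygen, the effect in light minus that in dark was largest at dnaJ, a chaperone gene, at -0.70 (-0.36 in light, 0.34 in dark). It was 0.60 at htr4 and -0.59 at htr18, transducer genes that were well above background on 1 array each. Other transducer genes gave 0.33 (htr8), 0.32 (htr7) and -0.089 (htr6). The chemotaxis genes cheA and cheR gave 0.18 and 0.15, pyrF gave 0.31, and sucD of the citric acid cycle gave -0.20.

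For light, the effect at high minus that at low oxygen was largest at pheS, a tRNA ligase gene, at -0.95 (-0.17 at high, 0.78 at low oxygen, above background on 4 arrays). It was 0.70 at dnaJ, -0.60 at htr4, 0.56 at purM of purine synthesis and -0.37 at uvrA of excision repair. It was -0.33 at htr8, 0.20 at sucD, 0.13 at ileS and -0.11 at cbiQ. At dnaJ, htr4, htr8 and sucD both effects flipped, which is the same difference seen from both sides.

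The ratio of sop2 near the reference is the pattern a biologist would follow up first. Wrongly joined gene names are argued against by the csg probe set, which lay at brightness percentile 100. A loss hidden by background correction or normalisation is argued against by the lowest sop2 mean of any alternative, -0.13 with loess within print blocks. Signal near background that hides a loss is argued against, since the culture channel at sop2 stood at 4.57 times its background on average, a level reached by 0.0662% of the 1511 probe sets that were above background in the reference on 0 arrays (0 to 12.5% of them on single arrays). A probe outside the deleted part, signal from a related transcript and a culture that kept the gene may also account for it, and none of these was tested.

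The Alexa 647 array of the low-oxygen dark culture correlated with the opposite dye orientation more than with its own, at 0.55 against 0.08, and in the deposited table at 0.81 against -0.57, which taken alone would go with a turned sign. Dyes exchanged against the labels are argued against, since 87.1% of 178 bright probe sets with 1 sign on the other 7 arrays had that sign here, close to the lowest share among the other arrays, 87.6%, and an exchange would turn these signs. When this array was fitted over all probe sets as a sum of a culture part and a dye part, both taken from the other 3 cultures, the culture part had a coefficient of 0.99 ± 0.04 (SE) in the deposited table and 1.27 ± 0.06 in the scanner values, where an exchange needs a negative one, and the dye part had -1.13 and -0.51. The high Alexa 647 background is a candidate explanation, since the correlation with its own orientation rose by 0.78 from the dimmest to the brightest 25% of probe sets, against 0.43 among the other arrays of that orientation, which meets its bound by a small margin. Against it, the median Alexa 647 intensity over background on this array was 2.28, within the 1.89 to 3.02 of the other arrays. Over bright probe sets the dye part of this array was 0.92 and its culture part 0.82 in the scanner values, as on arrays of its own orientation, but in the deposited table the dye part was still -0.41, so background may not be the whole cause, and no biological explanation was tested.

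The oxygen effects in light and in dark correlated below 0 over all probe sets, at -0.22. Independent noise of dim probe sets is argued against, since it gives about 0 and r was -0.228 over the probe sets not above background on all 8 arrays. Dye bias left uncancelled in the low-oxygen dark culture, whose arrays had dye parts of -1.42 and -0.51, is a candidate for the effect in dark alone. That effect correlated at -0.446 with the dye part of the light cultures. The effect in light correlated at 0.164 with the dye part of the high-oxygen dark culture. It does not use the low-oxygen dark culture, so this value cannot come from dye bias there, and its cause was not tested. With the dye part of these 3 cultures taken out of both effects r was -0.0871. Their arrays also make up the effects, so this step is no independent support. Over the bright probe sets r was 0.21 without this step and 0.19 with it. There the effect in dark and that in light correlated with these dye parts at -0.063 and -0.117, both below 0. An oxygen response that differs between light and dark stays open, as untested.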

How the results depend on the processing

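Of 233 values under alternatives, 186 stayed within their spread or, for counts, equal or close in size to the main count, and 47 moved. Many of the 186 were counts of 0 that stayed at 0. Why values moved was not tested. Added after seeing the data were each scan alone, loess within print blocks, spots of low confidence left out, bright probe sets alone, each dye orientation alone and all probe sets as list background. Signal over background limits most probe sets, since 519 of 2688 were well above it on all arrays. Of the named genes, 13 of 14 kept their sign against the reference under every alternative, 3 of 14 with oxygen and 6 of 15 with light. These genes were chosen for 1 sign in all single values. Leaving out an array could therefore not turn a sign against the reference, nor leaving out a culture one with oxygen or light. In these alternatives a kept sign is no support. In the deposited table the median of all genes was 0.10 against the reference, 0.11 with oxygen and -0.19 with light, where the main values gave 0.017, -0.0058 and -0.0055. In place of 0 probe sets against the reference, 444 passed with median centring, 7 in the deposited table, 284 with bright probe sets alone and 1054 with 8 arrays and a culture block. With median centring 1 passed for oxygen and 2 for light, and under the other alternatives 0. Lists passing against the reference were 2 in the deposited table (citric acid cycle, cobalamin synthesis), 1 with the low scan alone (citric acid cycle) and 1 by fry. With an estimated correlation, at which hardly any list could pass here, the camera calls had an adjusted p = 0.757, 0.757 and 0.784. For light 1 list, chemotaxis, passed with the low scan alone (adjusted p = 0.0313, and 0.745 with an estimated correlation).

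The sop2 ratio was -0.020 with median centring, 0.046 in the deposited table and -0.13 with loess within print blocks. The pyrF ratio was -0.23 without background correction, -0.78 with subtraction, -0.26 with median centring, -0.023 in the deposited table and -0.11 with the low scan alone. The correlation of oxygen effects was -0.57 in the deposited table and 0.21 over bright probe sets. That of light effects was -0.10 without background correction, -0.25 with dim probe sets left out and -0.13 with loess within print blocks. The large oxygen by light differences numbered 5 without background correction, 294 with median centring, 96 in the deposited table, 62 with dim probe sets left out, 10 with the low scan alone, 0 over bright probe sets, 300 in the Alexa 532 orientation alone, 457 in the Alexa 647 orientation alone and 289 at a size of 0.58.

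Leaving out single arrays gave 0 to 232 probe sets against the reference, a sop2 ratio of -0.10 to -0.018, 0 to 1 list for oxygen, a correlation of oxygen effects of -0.43 to 0.32 and of light effects of -0.50 to 0.47. Each of these leaves 1 culture with a single dye, so dye bias there is not cancelled. With 1 culture left out, an effect is the difference of 1 pair of cultures and has no test. An alternative that keeps spots marked as poor by the scanner was not run, since the tables hold no such marks. The fit itself sets oxygen levels against each other within light and within dark, and light against dark within each oxygen level. Beyond that, no paired analysis was possible because replicate numbers only name the arrays of a culture.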

Other observations

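The groups in this part were chosen after the values were seen, and none was tested as a group. Against the reference, the 3 measured genes of histidine use had positive means in the cultures labelled sop2 and ura3 knockouts: hutI 0.41, hutG 0.36 and hutU 0.23 (n = 4 cultures). They were well above background in the culture on 1, 1 and 0 arrays and in the reference on 0. The 6 genes of histidine synthesis went both ways, with 3 higher and 3 lower. Of the glutamate dehydrogenase genes, gdhA1 (-0.31 ± 0.05, limma SE) and gdhA2 (-0.26 ± 0.08, above background on 2 arrays) had negative means and gdhB a positive one (0.09 ± 0.05). The gyrase genes gyrA (-0.32 ± 0.10, single arrays from -0.61 to 0.23) and gyrB (-0.37 ± 0.05, above background on 1 array) had negative means. Among single genes well above background on all 8 arrays, speB, agmatinase of polyamine synthesis, had a ratio of -0.29 ± 0.05 and moaC of molybdenum cofactor synthesis one of 0.24 ± 0.05. With arcC, the arginine deiminase gene arcA stood above the reference, at 0.18 ± 0.05.

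The gene dpsA, of an iron-storing protein that guards DNA, stood at -0.21 ± 0.09 in light against dark and 0.03 ± 0.09 at low against high oxygen. The 3 thiamine synthesis genes had positive oxygen means, from 0.04 (thiC) to 0.24 (thiL). Of the purple membrane genes, both well above background on 1 array, bat stood at 0.52 ± 0.18 and hop at -0.09 ± 0.09 at low against high oxygen.

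Of the 155 bright probe sets with the same sign on all 8 arrays, 146 are unnamed here. The largest positive ratios among them were those of the probe sets that begin at probe 1605, at 1.04 ± 0.08, and probe 4845, at 0.64 ± 0.05. The most negative were those at probe 369, at -0.80 ± 0.05, and probe 337, at -0.70 ± 0.05.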
